A study of Solanum lycopersicum with 12 samples.

How the data were processed

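The series holds 12 RNA-seq libraries from the apical part of 4-week-old tomato plants, 4 each for the control, (Z)-3-hexenyl propanoate (Z3HP) and methyl salicylate (MeSA), grouped by the treatment and title in the labels. Per the labels' protocols, an intact plant was kept for 24 h in a cage with 2 filter-paper cards. Each card carried 10 µl of the volatile at a dilution of 1 in 10000 or, for the control, methanol and water. Cages stood in isolated climatic chambers at 25 °C with 14 h of light and 10 h of dark. Libraries were made with a stranded mRNA kit, per the labels' protocols. The labels number the libraries of a group as separate plants. The hour of harvest and the chamber of each group are not given in the sources used here, and neither is a sequencing batch.

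The deposited estimated counts per gene are whole numbers from StringTie 1.3.3b, run in its reference-only mode with strand information on gene models of the tomato build SL2.50, per the file headers. HISAT2 2.0.5, Bowtie2 2.2.6, Trimmomatic 0.32 and FastQC 0.11.5 were also named, per the submitters' processing notes, with no order or settings. The estimated counts as deposited equalled the StringTie coverage times transcript length over a read length of 101, rounded up, for 99.85% to 99.88% of 30376 entries per library, and within 1 for 99.94% to 99.96%. They are therefore estimates from coverage and not direct tallies of reads or fragments, and 61.3% to 65.3% of the values from 1 to 29 per library were even. Whether both mates of a read pair enter a count is not given in the sources used here, so totals can exceed the number of fragments and counting noise can be larger than the counts imply. The deposited values were already whole, so no further rounding was applied. The authors' FPKM values per gene, in the same deposited table, are StringTie's fragments per kilobase scaled to library size, per the file headers, and were used only as an alternative.

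Of the 30376 entries, 8 had no gene name and held plastid ribosomal RNA. They were left out of library sizes and tests, and took 3.86%, 5.43%, 4.62% and 7.03% of the counts in control replicates 1 to 4, 3.51%, 2.82%, 1.9% and 2.62% in Z3HP, and 3.95%, 3.9%, 5.61% and 2.1% in MeSA. The other 30368 were named genes, among them 25703 protein-coding genes and 2569 long non-coding RNAs, and 9831 were uncharacterized. Symbols, descriptions and coordinates are those of the authors' files on SL2.50. Total counts were 54967018, 47934036, 37613949 and 44975004 in control replicates 1 to 4, 43625088, 38353076, 44761825 and 41745767 in Z3HP, and 42967655, 41072988, 45941506 and 46850293 in MeSA. StringTie can share reads between near-identical copies, so levels of members of multigene families, such as light-harvesting, histone, small heat shock and ribosomal protein genes, are uncertain.

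Counts were tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F tests (two-sided) after TMM scaling and the filterByExpr filter, which kept 20109 genes. All 12 libraries entered 1 model with 3 groups and 9 residual degrees of freedom, with a common dispersion of 0.038. Comparisons were Z3HP against control, MeSA against control and Z3HP against MeSA, with Benjamini-Hochberg adjustment within each and a threshold of 0.05. TMM factors were 1.111, 1.097, 1.104 and 1.008 in the controls, 0.973, 0.954, 1.001 and 0.96 in Z3HP, and 0.911, 0.941, 0.991 and 0.971 in MeSA. The CPM values printed use library sizes with these factors. Standard errors of log2 fold changes were derived from the F statistic of the same model.

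Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM, adjusted over 69 tests of 23 lists in 3 comparisons. Members were tested genes matched by fixed word patterns in their descriptions or symbols, with uncharacterized genes left out, so a list can hold a gene whose name matches for another reason. The defence lists were jasmonate synthesis and signalling, proteinase inhibitors and other antiherbivore proteins, salicylate synthesis, methylation and signalling, pathogenesis-related proteins, green leaf volatiles and other oxylipins, terpenoid synthesis, phenylpropanoids with flavonoids and lignin, WRKY factors, and immune receptors and receptor kinases. The hormone and growth lists were ethylene synthesis and signalling, auxin response, abscisate and water deficit, photosynthesis, cell division, cell wall remodelling and ribosomal proteins. Heat shock proteins and chaperones, glutathione and glycosyl transferases, and circadian clock and day length made up the rest, with markers of shoot meristem, of flower, anther and pollen, of trichome and epidermis, and of root. The count of members past the threshold was also taken with p adjusted over the list alone.

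The genes named in each comparison with the controls followed a rule. It took the 8 higher and 8 lower genes with the largest log2 fold change among those past the threshold, with a mean of at least 1 CPM over the 12 libraries and all 4 exposed libraries on the same side of all 4 controls. It added up to 2 members of each list past the threshold with the smallest p, and 15 defence genes fixed as a panel whatever their result, each the matching gene of highest mean CPM. Between the volatiles it took 5 higher and 5 lower genes and 1 member per list. Uncharacterized genes were counted and not named. The comparisons, test, filter, lists, panel, naming rule and most other settings were chosen before the data were examined.

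The other settings tried were RLE and upper-quartile scaling, no low-count filter, CPM of at least 1 in 4 libraries, DESeq2 1.42.0, only the 2 groups compared, the replicate number as a block, each library left out in turn, limma on log2 FPKM with pseudocounts of 1 and 0.1 for genes of FPKM at least 1 in 4 libraries, and thresholds with a 2-fold change. For lists they were camera with an estimated correlation and fry, both in limma. Library sizes without scaling factors, Fisher's exact test (two-sided) of changed genes in either direction, counts outside the clock, photosynthesis and ribosomal protein lists, and the ethylene list without names containing methylene were added after the data were seen. Comparisons that share the controls were set against 20 simulations of unchanged groups and against 6 splits of the controls into separate pairs. Measures of whole libraries were compared by exact permutation tests. Enrichment of annotation terms was not run, since the files used here pair no terms with genes.

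Pairs of libraries within a group differed by 13.77 to 71.87 times the variance of counting noise, so no pair was treated as 1 library. The procedure was tested on simulated counts for 19897 genes. For Z3HP against control it recovered 22.7% of 66 genes changed by 0.5 on the log2 scale, 80.6% of 67 changed by 1 and 97% of 66 changed by 2, with 7 false calls among 19652 unchanged genes. For Z3HP against MeSA the shares were 24.2%, 76.1% and 97%, with 4 false calls. In the simulation, changes of 0.5 were therefore missed more often than found. A smaller share of genes was changed there than the 30%, 25.6% and 3.7% called in the 3 comparisons of the data. That makes the adjusted threshold stricter, so these shares need not carry over to the data. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.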

Results

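Messenger RNA was sequenced from the apical part of 4-week-old tomato plants (Solanum lycopersicum, cultivar Moneymaker) in 3 groups of 4 libraries each. Plants spent 24 h in cages with filter papers carrying a diluted compound. One group received (Z)-3-hexenyl propanoate, an ester of the green leaf volatile family, here called Z3HP. A further group received methyl salicylate, here called MeSA, the volatile methyl ester of the defence hormone salicylate. The controls received the methanol and water mixture. The design text asks how expression differs between plants exposed to either volatile and plants that were not exposed. The title places the work among volatiles that plants release under herbivore attack and that can elicit defences. Estimated counts per library summed to 37613949 to 54967018 in the controls, 38353076 to 44761825 in Z3HP and 41072988 to 46850293 in MeSA. Of 30368 named genes, 20109 had enough counts to be tested. Levels are in CPM, counts scaled to a common library size, as mean ± SD over n = 4 libraries. Log2 fold changes are given with their standard error, and a gene is said to have risen, fallen or changed where edgeR's adjusted p was under 0.05.

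The controls stood apart from both exposed groups. On the first principal component, which held 33.3% of the variance, the controls lay between -58.64 and -48.81 and all 8 exposed libraries between 19.14 and 38.77. Control replicate 4 stood away from the other controls on the second component, at -49.53 against 7.66 to 14.49. Its log2 levels correlated with those of the other controls at 0.963 to 0.965 across genes, against 0.974 to 0.979 among the other controls. Plastid ribosomal RNA took 5.24% ± 1.36 of the counts in the controls, 2.71% ± 0.66 in Z3HP and 3.89% ± 1.43 in MeSA (SD, n = 4 each), with 7.03% in control replicate 4. The share was lower in Z3HP than in the controls at a two-sided exact permutation p = 0.0286, the smallest that 70 assignments give, and at 0.103 after adjustment over 18 such library tests.

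**Figure D1:**
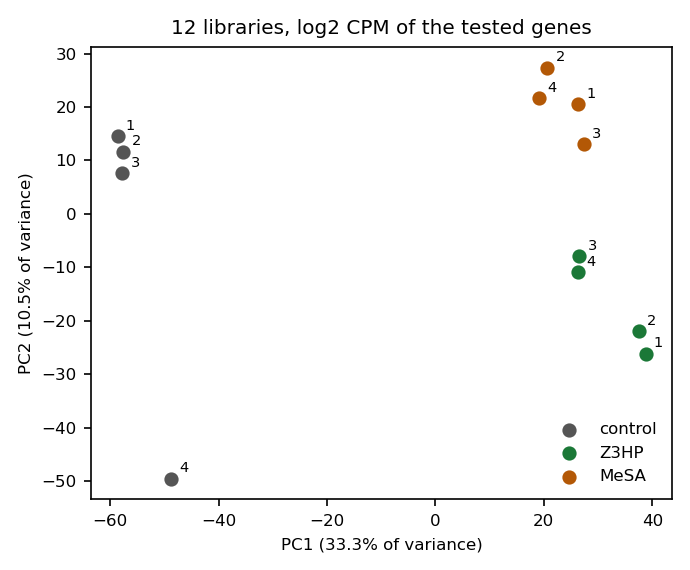
Principal components of log2 CPM over the tested genes, with 1 point per library and the replicate number beside it; the x axis holds 33.3% and the y axis 10.5% of the variance. The 4 controls lie at -58.64 to -48.81 on the x axis and the 8 exposed libraries at 19.14 to 38.77, and control replicate 4 lies at -49.53 on the y axis.

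The first comparison asked which transcripts differed after exposure to Z3HP. The CONSTANS-LIKE 16-like zinc finger gene LOC101253781 (chromosome 5, 3442956 to 3445261, build SL2.50) went from 57.1 ± 4.12 CPM in controls to 0.818 ± 0.465 in Z3HP, 69.7-fold lower (log2 -6.12 ± 0.35, edgeR adjusted p = 1.81e-08). The pseudo-response regulator APRR1 (LOC101259425, chromosome 3, 65377400 to 65384090), a relative of the evening clock component TOC1, fell from 54.8 ± 2.74 to 1.82 ± 1.06 CPM, 30.4-fold. The other APRR1 gene (LOC101259163) fell by 0.44 on the log2 scale (edgeR adjusted p = 0.0385). Among the genes taken by the naming rule the largest rise was in 20ox-2 (chromosome 6, 24482300 to 24484611), a gibberellin 20-oxidase of hormone synthesis, from 0.124 ± 0.0306 to 4.04 ± 1.49 CPM (log2 5.02 ± 0.33, edgeR adjusted p = 7.97e-08). The cytochrome P450 71A1-like gene LOC101251878 rose 29.7-fold, from 2.9 ± 0.505 to 85.7 ± 10.7 CPM.

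In all, 6039 of 20109 genes (30%) changed in Z3HP against the controls, 3027 higher and 3012 lower, and 1388 of them by at least 2-fold, 867 higher and 521 lower. The other leading risers were the transcription factor RAV1 (LOC101259430, log2 4.66 ± 0.50), the Hop-interacting protein THI121 (LOC101055534, 4.42 ± 0.20) and proteinase inhibitor I-B (LOC101265368). They also included the blue-light receptor family member TWIN LOV 1-like (LOC101255122, 4.03 ± 0.27), boron transporter 4 (LOC101253069, 3.90 ± 0.26) and the sugar transporter STP11 (3.81 ± 0.32). The other leading fallers were the JmjC-domain gene JMJ524 (-5.46 ± 0.61), CONSTANS-LIKE 9-like (LOC101257930, -4.84 ± 0.51) and the putative zinc finger gene LOC101253772 (-4.82 ± 0.18). Next came sucrose-phosphate synthase B (LOC101055573, -4.49 ± 0.22), high mobility group B protein 9 (LOC101249807, -3.95 ± 0.26) and CO3 (CONSTANS 3, -3.77 ± 0.54). Every one of these genes passed with all 4 exposed libraries on the same side of all 4 controls, as the rule for naming them required.

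Clock and day-length genes moved in both directions. Of 60 tested, 22 rose and 23 fell, 23 and 24 when adjusted over the list alone. Both LNK1 genes, coactivators of the morning clock loop, rose, LOC101244909 from 49.8 ± 6.65 to 208 ± 18.7 CPM and LOC101266410 from 23.6 ± 2.45 to 91.6 ± 7.9. Fisher's exact test (two-sided) put changed genes in this list above the rest of the tested genes (adjusted p = 9.52e-12). Camera, which asks for 1 direction, did not call it (adjusted p = 0.975). Among evening genes chosen after their values were seen, PCL1 fell by 2.72 on the log2 scale, EARLY FLOWERING 4 (LOC101267898) by 2.17 and GIGANTEA (LOC101255788) by 0.43. Other evening genes rose, PCL1-like (LOC101265183) by 0.60 and an EARLY FLOWERING 3 gene (LOC101268174) by 0.66, and EARLY FLOWERING 4-like (LOC101256003, 0.22) and PCL1-like (LOC101249222, -0.31) did not pass.

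Photosynthesis genes rose together, 51 of 89, with 9 lower, and 52 and 10 when adjusted over the list alone (camera adjusted p = 1.60e-12; adjusted p = 0.284 with an estimated correlation). The light-harvesting gene CAB12 rose from 885 ± 126 to 3690 ± 93.2 CPM and chlorophyll a-b binding protein 6A (LOC101253380) from 895 ± 69.9 to 2390 ± 119. Ribosomal protein genes fell, 232 of 343 with 7 higher, and 244 and 7 over the list alone (camera adjusted p = 8.54e-20; adjusted p = 0.284 with an estimated correlation). The nuclear gene for the chloroplastic 50S ribosomal protein L15 (LOC101255295) fell from 352 ± 22.8 to 162 ± 18.9 CPM and plastid-specific ribosomal protein 5-like (LOC101252938) from 636 ± 35.1 to 342 ± 22.5. Of 192 cell division genes 65 fell and 19 rose, 70 and 21 over the list alone (camera adjusted p = 0.00654; adjusted p = 0.614 with an estimated correlation), among them a histone H2B-like gene (LOC101244346, -0.87 ± 0.09) and, rising, cyclin-U2-1 (LOC101268514, 1.09 ± 0.13).

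Camera called 4 hormone lists upward, although 33 of 46 jasmonate, 74 of 112 abscisate, 78 of 115 auxin and 86 of 118 ethylene genes did not pass. Fisher's exact test did not call their shares of changed genes different from the rest (adjusted p = 1, 0.78, 0.89 and 0.89). Of 46 jasmonate genes 12 rose and 1 fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.00761; adjusted p = 0.208 with an estimated correlation). MYC2, the transcription factor at the centre of jasmonate responses, rose from 15 ± 1.96 to 32.3 ± 1.92 CPM. The TIFY 4B-like gene LOC101259854 fell from 7.42 ± 0.235 to 3.15 ± 0.33. Of 112 abscisate and water deficit genes 33 rose and 5 fell, 33 and 6 over the list alone (camera adjusted p = 0.00153; adjusted p = 0.284 with an estimated correlation). Protein phosphatase 2C 53 (LOC101258862) rose by 2.55 ± 0.20 and Asr4 by 1.10 ± 0.10. Of 115 auxin response genes 28 rose and 9 fell, 29 and 9 over the list alone (camera adjusted p = 0.0147; adjusted p = 0.38 with an estimated correlation). IAA4 rose by 1.72 ± 0.14 and the auxin repressed gene LOC101258429 by 2.82 ± 0.23. Of 118 ethylene genes 26 rose and 6 fell, 24 and 6 over the list alone (camera adjusted p = 0.0236; adjusted p = 0.208 with an estimated correlation). ERF4, an ethylene response factor, rose from 13.5 ± 5.58 to 114 ± 17.3 CPM. The other ethylene gene taken by the naming rule, LOC101243835 (1.60 ± 0.15), is a methylenesterol methyltransferase of sterol synthesis that matched by its name. Without 6 such members the list stood at 24 higher and 6 lower of 112 (camera adjusted p = 0.0322).

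Defence products moved unevenly in Z3HP. Proteinase inhibitor I-B (LOC101265368), a protein that blocks digestive enzymes of herbivores, rose from 1.25 ± 0.693 to 22 ± 11.7 CPM (log2 4.15 ± 0.49, edgeR adjusted p = 2.04e-05). Wound-induced proteinase inhibitor 1 (LOC101246961) fell from 18.1 ± 0.757 to 9.13 ± 2.49 and the metallocarboxypeptidase inhibitor-like gene LOC101253698 fell by 0.45 on the log2 scale. In that list 4 genes rose and 5 fell of 37, the same over the list alone. HPL, the hydroperoxide lyase that makes green leaf aldehydes, rose from 28.4 ± 5.66 to 79.1 ± 8.62 CPM, and dxs, at the entry of plastid terpenoid synthesis, from 212 ± 23.7 to 605 ± 33.1. Among salicylate genes 9 of 36 rose and 0 fell by edgeR, the same over the list alone, against 11 and 2 at an unadjusted p under 0.05. DESeq2 called 10 and 0, and limma on FPKM 7 and 1. EDS1 of disease resistance signalling (1.08 ± 0.11) and DMR6-LIKE OXYGENASE 2 (LOC101250715, 1.67 ± 0.19) were among the risers. Camera did not call the list (adjusted p = 0.089) except without Z3HP replicate 1 (adjusted p = 0.0398). Of the fixed panel of defence genes, threonine deaminase (LOC100037737, 0.51 ± 0.09), polyphenol oxidase E (LOC101259357, 0.91 ± 0.22), loxD of jasmonate synthesis (0.51 ± 0.12) and NIM1, the tomato NPR1 (0.55 ± 0.12), also rose. AOS2 (0.08 ± 0.12), opr3 (-0.08 ± 0.10), a glucan endo-1,3-beta-glucosidase (LOC101249056, 0.00 ± 0.09) and salicylic acid-binding protein 2 (LOC101261578, 0.28 ± 0.16) did not pass.

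The last 5 panel genes each passed when 1 library was left out. They were wound-induced proteinase inhibitor 2-like (LOC101255652, -0.34 ± 0.23, and -0.62 without Z3HP replicate 4, edgeR adjusted p = 0.03) and pathogenesis-related leaf protein 4-like (LOC101265854, 0.66 ± 0.31, and 0.86 without Z3HP replicate 1, adjusted p = 0.0459). SAMT stood at 0.37 ± 0.16, and at 0.51 without control replicate 3 (edgeR adjusted p = 0.0301). Without control replicate 4, chitinase-like protein 1 (LOC101254426) went from 0.20 ± 0.10 to 0.32 (edgeR adjusted p = 0.00504) and PAL3 from 0.26 ± 0.17 to 0.48 (adjusted p = 0.0163).

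The remaining lists were mixed. Glutathione and glycosyl transferases, which conjugate small molecules, had 37 higher and 15 lower of 144, the same over the list alone (camera adjusted p = 0.0491; adjusted p = 0.284 with an estimated correlation). They were led by UDP-glycosyltransferase 91A1-like (LOC101245147, 1.73 ± 0.09) and LOC543836 (1.74 ± 0.10). The list call was lost without control replicate 1, 3 or 4, Z3HP replicate 1, 2 or 3, or MeSA replicate 1, 2 or 4 (camera adjusted p = 0.054 to 0.0831), and with RLE factors (0.0551). Phenylpropanoid genes had 29 higher and 10 lower of 113, with flavonoid 3'-monooxygenase-like (LOC101267831) at 2.25 ± 0.11 and an anthocyanidin xylosyltransferase-like gene (LOC101256480) at 2.22 ± 0.09. Heat shock genes had 11 higher and 24 lower of 80, the first led by a heat shock protein binding protein (LOC100736525, 3.67 ± 0.19) and a DNAJ-domain gene (LOC101268200, 1.57 ± 0.13). Camera called neither list (adjusted p = 0.0624 and 0.327), although phenylpropanoids passed without Z3HP replicate 3 (adjusted p = 0.0448). Fisher's exact test put changed genes above the rest for heat shock (adjusted p = 0.0426) and cell wall genes (0.0441). Camera called none of the following. The numbers higher and lower were 16 and 18 of 99 pathogenesis-related genes, 5 and 2 of 12 green leaf volatile genes, 9 and 2 of 39 terpenoid genes, 7 and 2 of 49 WRKY genes, 44 and 38 of 215 cell wall genes and 67 and 48 of 451 immune receptor genes. The terpenoid list passed without control replicate 2 or 4, Z3HP replicate 1 or 2, or MeSA replicate 3 (camera adjusted p = 0.027 to 0.0492), and with upper-quartile scaling (0.046). Among markers of other tissues they were 5 and 2 of 29 meristem, 13 and 5 of 57 flower and pollen, 22 and 8 of 102 trichome and epidermis and 4 and 2 of 17 root genes. The root list's leading members were early nodulin-like protein 2 (LOC101251653, 2.33 ± 0.10) and nodulin-related protein 1 (LOC101249727, 2.03 ± 0.09), whose names come from legume nodules. Camera's direction was up for the cell wall list (median -0.019, mean -0.01) and the root list (median -0.05, mean 0.167), so these signs differed.

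Examples from those lists were chitinase 2-like (LOC101256061, -2.38 ± 0.22) and a PR-1-like gene (LOC101267821, 0.94 ± 0.12), linoleate 9S-lipoxygenase-like (LOC107648852, -0.61 ± 0.10) and a hydroxymethylglutaryl-CoA lyase (LOC101259975, 0.91 ± 0.12). The lyase entered the terpenoid list by the words hydroxymethylglutaryl-CoA in its name. Others were WRKY transcription factor 3 (LOC100191121, 1.51 ± 0.11) and 1 (LOC100301944, 1.25 ± 0.10), expansin12 (LOC543795, -1.79 ± 0.11) and pectinesterase 12 (LOC101261415, 1.88 ± 0.11). The receptor-like kinase genes LOC101266040 (2.36 ± 0.12) and LOC101259524 (1.23 ± 0.09) and the knotted-like genes T12 (0.68 ± 0.07) and LOC101261052 (0.72 ± 0.10) rose. So did TAPETUM DETERMINANT 1-like (LOC101255145, 1.79 ± 0.18), the APETALA2 gene LOC101258696 (1.34 ± 0.14), a lipid-transfer family gene (LOC101245586, 1.82 ± 0.13) and trichome birefringence-like 25 (LOC101243939, 0.99 ± 0.10). The share of higher genes rested on the scaling: it was 50.1% with TMM factors, 28.6% with library sizes alone, and 34.3% and 34.5% on the authors' FPKM with pseudocounts of 1 and 0.1. In those settings the median of all genes lay at -0.168, -0.099 and -0.118, against -0.016 with TMM. Under library sizes alone the abscisate and glutathione lists had medians of -0.012 and -0.024, which lay 0.156 and 0.144 above that of all genes. The terpenoid, phenylpropanoid and flower lists passed in that setting (camera adjusted p = 0.0243, 0.0188 and 0.0394). The balance of higher and lower members turned under library sizes alone for cell wall (35 and 62) and immune receptor genes (42 and 86) and for flower (8 and 9), trichome (13 and 15) and root markers (2 and 4). By limma on FPKM cell wall genes stood at 34 and 50 and immune receptor genes at 38 and 59, and with upper-quartile scaling cell wall genes at 42 and 43. Other lists under library sizes alone stood at 6 and 2 (salicylate), 13 and 25 (pathogenesis-related), 22 and 17 (phenylpropanoid), 18 and 11 (ethylene), 5 and 4 (WRKY) and 19 and 15 (auxin). There, too, 26 and 10 abscisate, 12 and 91 cell division, 7 and 29 heat shock and 33 and 23 glutathione genes passed.

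The second comparison asked the same of MeSA. Among the genes taken by the naming rule, the 3 largest falls were in day-length and clock genes. LOC101253781 (CONSTANS-LIKE 16-like) stood at 0.918 ± 0.448 CPM against 57.1 ± 4.12 in the controls, 62.4-fold lower (log2 -5.96 ± 0.34, edgeR adjusted p = 2.33e-08). CONSTANS-LIKE 9-like (LOC101257930) was 49.9-fold lower and APRR1 (LOC101259425) 44-fold lower. The former lay at 3.15 CPM in control replicate 1 and at 12.9 to 16.7 in the other controls. The other APRR1 gene (LOC101259163) stood at -0.37 on the log2 scale and did not pass (edgeR adjusted p = 0.0906). REVEILLE 1 (LOC101261079, chromosome 2, 30601561 to 30604357), a MYB factor under clock control, fell from 92.3 ± 15.3 to 5.01 ± 0.95 CPM (-4.20 ± 0.17, edgeR adjusted p = 1.37e-09). The gibberellin gene 20ox-2 rose from 0.124 ± 0.0306 to 3.42 ± 0.571 CPM (4.78 ± 0.33) and the P450 gene LOC101251878 from 2.9 ± 0.505 to 63.7 ± 9.14 (4.46 ± 0.15).

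Of 20109 genes 5143 (25.6%) changed in MeSA against the controls, 2534 higher and 2609 lower, and 1086 by at least 2-fold, 643 higher and 443 lower. The other leading risers were RAV1 (LOC101259430, 4.77 ± 0.49), dormancy-associated protein 1 (LOC101257929, 4.24 ± 0.66) and a light-regulated protein (LOC101268227, 3.83 ± 0.23), followed by TWIN LOV 1-like (LOC101255122, 3.79 ± 0.27), THI121 (LOC101055534, 3.75 ± 0.20) and UNE10-like (LOC101260653, 3.63 ± 0.15). The other leading fallers were high mobility group B protein 9 (LOC101249807, -5.27 ± 0.29), sucrose-phosphate synthase B (LOC101055573, -5.16 ± 0.23), the zinc finger gene LOC101253772 (-4.71 ± 0.18), CO3 (-4.54 ± 0.58) and JMJ524 (-4.53 ± 0.55). Of 60 clock genes 19 rose and 21 fell, 19 and 25 when adjusted over the list alone. That was above the share among other genes by Fisher's exact test (adjusted p = 2.56e-10) but without 1 direction (camera adjusted p = 0.451). LNK1 (LOC101244909) rose to 180 ± 7.24 CPM (1.85 ± 0.10).

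**Figure D2:**
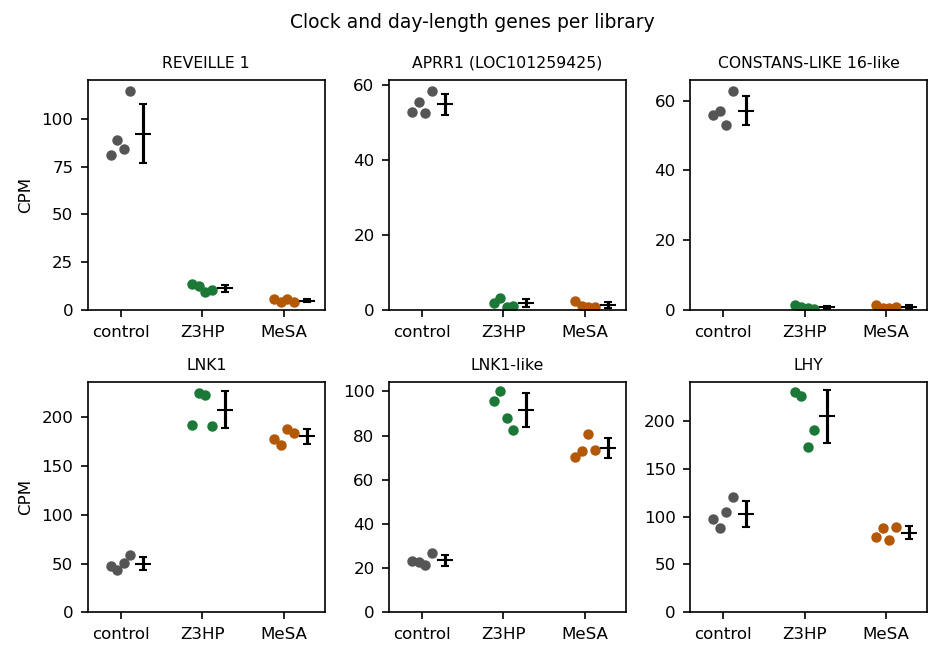
CPM of 6 clock and day-length genes in each library (points), with the mean and SD of the 4 libraries per group as bars, on linear axes from 0. REVEILLE 1, APRR1 and CONSTANS-LIKE 16-like were lower in both exposed groups than in all 4 controls, LNK1 and LNK1-like were higher, and LHY had means of 103 in the controls, 205 in Z3HP and 83 in MeSA.

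Photosynthesis genes rose in MeSA, 53 of 89 with 8 lower, and 53 and 9 over the list alone (camera adjusted p = 6.67e-14; adjusted p = 0.284 with an estimated correlation). CAB12 stood at 2990 ± 157 CPM (1.76 ± 0.10) and CAB6A at 6800 ± 245 against 2750 ± 141 (1.3 ± 0.07). Ribosomal protein genes fell, 173 of 343 with 8 higher, and 192 and 10 over the list alone (camera adjusted p = 7.04e-13; adjusted p = 0.413 with an estimated correlation). LOC101252938 stood at -0.82 ± 0.08 and 50S ribosomal protein 6 (LOC101246627) at -0.95 ± 0.10. Heat shock genes rose, 26 of 80 with 9 lower, and 29 and 11 over the list alone (camera adjusted p = 0.0271; adjusted p = 0.284 with an estimated correlation). BAG6 (LOC101246665, chromosome 1, 86628614 to 86633696), a chaperone regulator, rose 9.05-fold from 16.7 ± 3.4 to 151 ± 62 CPM, and LOC100736525 10.1-fold. HSP90 lay at 9.18 CPM in control replicate 4, below the other controls. Without that library the list stood at 26 higher and 12 lower of 82 and was no longer called (camera adjusted p = 0.0937), nor was it without MeSA replicate 2 (adjusted p = 0.0538). The balance of higher and lower members rested on the scaling, with 18 and 19 under library sizes alone and 18 and 16 by limma on FPKM.

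Jasmonate genes had 10 higher and 2 lower of 46, the same over the list alone (camera adjusted p = 0.0236; adjusted p = 0.254 with an estimated correlation). MYC2 stood at 27.6 ± 1.6 CPM (0.89 ± 0.10) and cytochrome P450 94A1-like (LOC101249297) at 1.78 ± 0.19. Abscisate and water deficit genes had 29 higher and 6 lower of 112, and 30 and 7 over the list alone (camera adjusted p = 0.0242; adjusted p = 0.475 with an estimated correlation). Protein phosphatase 2C 53 (LOC101258862) rose by 2.31 ± 0.20 and Asr4 by 1.11 ± 0.10. Without control replicate 1 both list calls were lost, each with a camera adjusted p = 0.0678, and without MeSA replicate 1 that of jasmonate (adjusted p = 0.0501). The abscisate median fell below 0 under library sizes alone (-0.056) and on log FPKM (-0.031), where it still lay 0.14 and 0.104 above that of all genes. Under library sizes alone 19 abscisate genes were higher and 21 lower, and 9 and 6 jasmonate genes. By limma on FPKM these were 19 and 18, and 7 and 5.

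Defence products in MeSA included proteinase inhibitor I-B (LOC101265368), up from 1.25 ± 0.693 to 14 ± 6.86 CPM (3.50 ± 0.48, edgeR adjusted p = 9.27e-05). Also higher were threonine deaminase (LOC100037737, 0.69 ± 0.09), HPL (1.17 ± 0.13), dxs (1.43 ± 0.08), EDS1 (1.07 ± 0.11) and loxD (0.41 ± 0.12). SAMT, which makes methyl salicylate from salicylate, rose from 9.42 ± 2.04 to 17.2 ± 3.35 CPM (0.87 ± 0.16, edgeR adjusted p = 0.00117). Chitinase-like protein 1 (LOC101254426) rose by 0.30 ± 0.10, a call lost without control replicate 1, 2 or 3 or MeSA replicate 1, 3 or 4 (edgeR adjusted p = 0.0571 to 0.104). The loxD call was lost without control replicate 1 (edgeR adjusted p = 0.0618) or MeSA replicate 2 (0.0559). Under library sizes alone both were lost too (edgeR adjusted p = 0.233 and 0.169). Wound-induced proteinase inhibitor 1 (LOC101246961) fell by 0.72 on the log2 scale. Polyphenol oxidase E (LOC101259357, 0.54 ± 0.22) and NIM1 (0.31 ± 0.12) did not pass by edgeR, but did with DESeq2 (adjusted p = 0.038 and 0.0442). Polyphenol oxidase E also passed without control replicate 2 (0.70, edgeR adjusted p = 0.0419), and NIM1 without control replicate 4 (0.39, adjusted p = 0.0342). AOS2 (-0.29 ± 0.12) and opr3 (-0.17 ± 0.10) passed as lower under library sizes alone (edgeR adjusted p = 0.00249 and 0.0102), not with TMM. Of the rest of the panel, salicylic acid-binding protein 2 (LOC101261578, 0.12 ± 0.16), the glucosidase LOC101249056 (0.01 ± 0.09), LOC101265854 (-0.05 ± 0.31), PAL3 (-0.19 ± 0.17) and LOC101255652 (-0.44 ± 0.23) did not pass.

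Camera called no other list in MeSA against the controls. Fisher's exact test put changed genes above the rest for heat shock (adjusted p = 0.0025), glutathione and glycosyl transferase (0.00792) and phenylpropanoid genes (0.0154). The numbers higher and lower were 4 and 3 of 37 proteinase inhibitor genes, 9 and 3 of 36 salicylate, 11 and 14 of 99 pathogenesis-related, 2 and 2 of 12 green leaf volatile and 7 and 1 of 39 terpenoid genes. They were 17 and 26 of 113 phenylpropanoid, 22 and 10 of 118 ethylene, 5 and 8 of 49 WRKY and 17 and 7 of 115 auxin genes. They were 15 and 39 of 192 cell division, 29 and 25 of 144 glutathione and glycosyl transferase, 42 and 28 of 215 cell wall and 51 and 53 of 451 immune receptor genes. Among tissue markers 6 and 2 of 29 meristem, 9 and 8 of 57 flower, 14 and 13 of 102 trichome and 4 and 2 of 17 root markers passed. Median, mean and camera direction differed in sign for green leaf volatiles (-0.098, 0.054, up), cell wall (-0.019, -0.019, up), meristem (-0.103, -0.005, up), flower (0.028, -0.065, up) and root genes (-0.043, 0.135, up). Without control replicate 4 the auxin and cell division lists passed as well (camera adjusted p = 0.0492 and 0.017), and the ethylene list did under library sizes alone (0.0395, with a median of -0.096). In that setting the balance turned for proteinase inhibitor (3 and 7), salicylate (5 and 7), auxin (12 and 18), glutathione (24 and 29) and cell wall genes (26 and 54) and for meristem (3 and 6), flower (4 and 10) and trichome markers (6 and 25). Immune receptor genes stood at 25 and 96 there, and by limma on FPKM at 17 and 69, with cell wall genes at 28 and 45. Other lists under library sizes alone stood at 6 and 26 (pathogenesis-related), 6 and 4 (terpenoid), 12 and 36 (phenylpropanoid), 17 and 17 (ethylene) and 4 and 11 (WRKY). The same setting gave 6 and 76 cell division, 17 and 29 clock and 2 and 2 root genes.

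Among members of these lists ERF4 stood at 2.65 ± 0.21, the ethylene-forming oxidase LOC100125909 at 1.42 ± 0.12 and the auxin-induced gene LOC101248844 at -3.91 ± 0.31. Chitinase 2-like (LOC101256061) stood at -3.20 ± 0.23 and CHI1 of flavonoid synthesis, which entered the pathogenesis list by its symbol, at -0.66 ± 0.10. The cell wall list held pectinesterase-like LOC101260197 at 2.69 ± 0.19 and pectate lyase 13 (LOC101264881) at -2.29 ± 0.16. The share of higher genes was 49.3% with TMM factors, 23% with library sizes alone, and 26.2% and 26.7% on FPKM with pseudocounts of 1 and 0.1. In those settings the median of all genes lay at -0.196, -0.135 and -0.159. Exposure took place in isolated chambers. Which chamber and hour of harvest belonged to each group is not given in the sources used here, so neither comparison with the controls separates exposure from these.

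**Figure D3:**
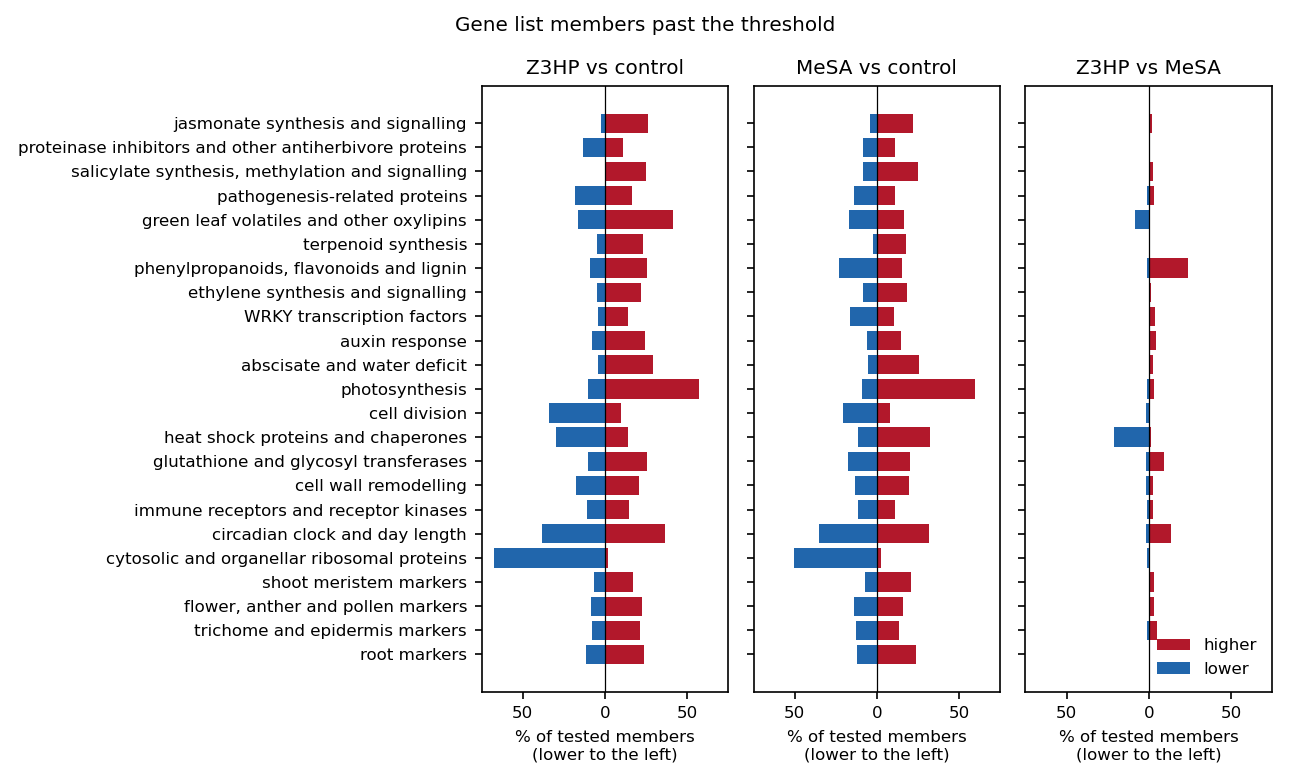
Percent of the tested members of each of the 23 gene lists that were higher (red, to the right) or lower (blue, to the left) at an adjusted p under 0.05, in each of the 3 comparisons. Against the controls, photosynthesis genes were mostly higher (51 and 53 of 89) and ribosomal protein genes mostly lower (232 and 173 of 343), while clock genes went both ways (22 higher and 23 lower, and 19 and 21, of 60). Between Z3HP and MeSA 27 of 113 phenylpropanoid genes were higher and 17 of 80 heat shock genes lower.

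Both volatiles were set against the same controls, and 3814 genes changed in the same direction in both, 1979 higher and 1835 lower, while 17 changed in opposite directions. Independent lists of these sizes would share 381.4 higher and 390.8 lower genes. In 20 simulations of unchanged groups against the same controls 0 genes passed in both by edgeR. Unchanged groups give almost no calls at this threshold, so that 0 does not gauge the overlap. The simulated fold changes correlated at a mean r of 0.495 across genes against 0.825 observed. Their covariance was 0.047 against 0.321, a difference of 0.275, and 66.5% against 79.6% of genes had the same sign in both. With the controls split into separate pairs the overlap averaged 2388.8 genes over 6 splits (2292 to 2547), r averaged 0.603 and the covariance 0.318. Genes are not independent replicates in these correlations. LOC101253781, APRR1 (LOC101259425), 20ox-2, CAB12 and MYC2 were among the genes that moved alike. Passing in 1 comparison alone is not a tested difference between the volatiles. Of 2208 genes past the threshold only with Z3HP 268 differed between Z3HP and MeSA, and of 1312 past it only with MeSA 200 did.

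The third comparison set the volatiles against each other, without use of the control means. BAG6 (LOC101246665) stood at 14.8 ± 3.97 CPM in Z3HP and 151 ± 62 in MeSA, 10.2-fold lower (log2 -3.35 ± 0.28, edgeR adjusted p = 5.26e-05), with 16.7 ± 3.4 in the controls. HSP90 (chromosome 6, 25803073 to 25806418), a chaperone of many signalling proteins, stood at 8.61 ± 1.24 and 37.9 ± 2.91 CPM (-2.14 ± 0.18, edgeR adjusted p = 5.26e-05), with 15.1 ± 3.96 in the controls. CHS1 (chromosome 9, 70775199 to 70777297), chalcone synthase at the entry of the flavonoid pathway, stood at 45 ± 7.07 CPM in Z3HP, 22 ± 2.65 in MeSA and 50.6 ± 5.11 in the controls. It was 2.05-fold higher in Z3HP than in MeSA (1.03 ± 0.12, edgeR adjusted p = 6.11e-04). The clock gene LHY (LOC101261662) stood at 205 ± 27.7 against 83 ± 6.72 (1.3 ± 0.11), with 103 ± 13.6 in the controls.

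**Figure D4:**
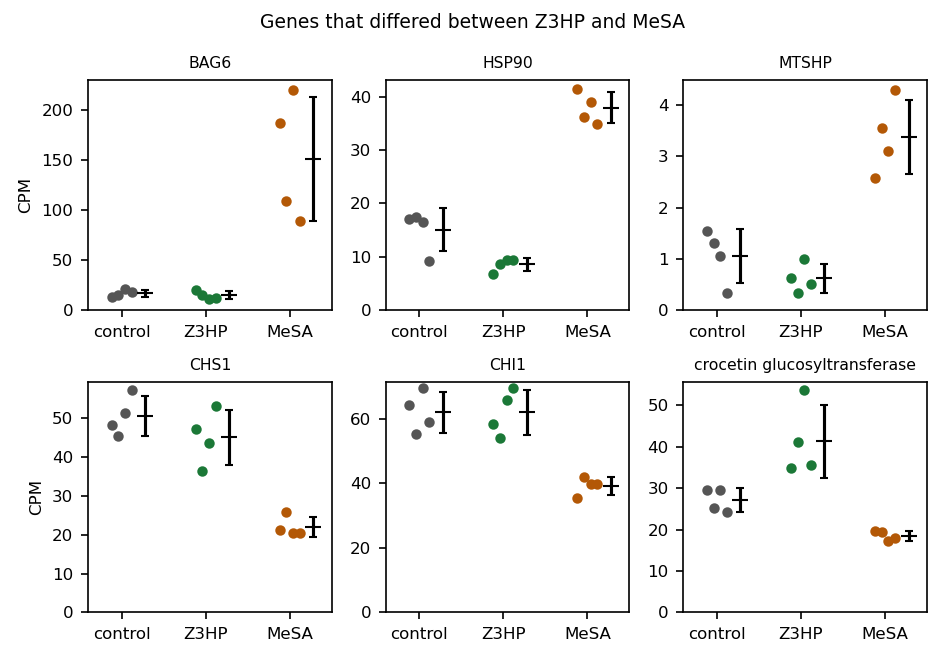
CPM of 6 genes that differed between the volatiles in each library (points), with the mean and SD of the 4 libraries per group as bars, on linear axes from 0. BAG6, HSP90 and MTSHP were highest in MeSA (means of 151, 37.9 and 3.38), and CHS1, CHI1 and the crocetin glucosyltransferase-like gene lowest there (means of 22, 39.2 and 18.5).

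Of 20109 genes 745 (3.7%) differed between Z3HP and MeSA, 487 higher in Z3HP and 258 lower, 83 of them by at least 2-fold (45 higher, 38 lower). The other leading genes higher in Z3HP were the inactive poly(ADP-ribose) polymerase family gene SRO2 (LOC101248971, 2.5 ± 0.32), hyoscyamine 6-dioxygenase-like (LOC101266893, 1.90 ± 0.28) and basic helix-loop-helix protein A (LOC101254527, 1.72 ± 0.32), then an SPX-domain membrane protein (LOC101265772, 1.59 ± 0.30) and endochitinase 4 (LOC101267358, 1.57 ± 0.36). The other leading genes lower in Z3HP were the mitochondrial small heat shock protein MTSHP (-2.42 ± 0.40), glutaredoxin-S1-like (LOC101251769, -2.06 ± 0.54, edgeR adjusted p = 0.0499) and the ripening regulated gene DDTFR8 (-1.97 ± 0.16). The glutaredoxin call was lost when any 1 library except control replicate 4 or Z3HP replicate 4 was left out (edgeR adjusted p = 0.0518 to 0.14), and with RLE factors (0.0515). The endochitinase call was lost without Z3HP replicate 1 or 3 or any 1 of the 4 MeSA libraries (adjusted p = 0.0538 to 0.0907).

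Phenylpropanoid, flavonoid and lignin genes were higher in Z3HP, 27 of 113 with 1 lower, and 44 and 2 when adjusted over the list alone (camera adjusted p = 3.42e-12). This was the only list call of the 3 comparisons that held with an estimated correlation (adjusted p = 1.46e-04). The 27 genes became 12, 16 and 15 without MeSA replicates 1, 2 and 4 and 14 without Z3HP replicate 2. The list had 29 higher and 10 lower genes in Z3HP, and 17 and 26 in MeSA, against the controls. Members chosen after their values were seen span the pathway: PAL5 at its entry (0.58), F3H (0.80) and a dihydroflavonol reductase (LOC544150, 1.18) on the flavonoid branch, and AnthOMT, which methylates anthocyanins (1.54). CHI1 stood at 62 ± 7.04 CPM in Z3HP, 39.2 ± 2.79 in MeSA and 62 ± 6.27 in the controls. Heat shock genes were lower in Z3HP, 17 of 80 with 1 higher, and 25 and 4 over the list alone (camera adjusted p = 2.57e-07; adjusted p = 0.0502 with an estimated correlation).

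The other called lists rested on smaller shifts. Glutathione and glycosyl transferases had 13 higher and 2 lower of 144, and 19 and 2 over the list alone (camera adjusted p = 0.00266; adjusted p = 0.252 with an estimated correlation), led by a crocetin glucosyltransferase-like gene (LOC101254109, 41.3 ± 8.76 against 18.5 ± 1.18 CPM). Clock genes had 8 higher and 1 lower of 60, and 13 and 4 over the list alone (camera adjusted p = 0.0236; adjusted p = 0.4 with an estimated correlation), and lost the call without Z3HP replicate 1 (adjusted p = 0.0686) or 2 (0.0897). WRKY factors had 2 higher of 49, and 5 over the list alone (camera adjusted p = 0.00114; adjusted p = 0.284 with an estimated correlation), with WRKY transcription factor 1 (LOC100301944) at 0.76 ± 0.09. Trichome and epidermis markers had 5 higher and 1 lower of 102, the same over the list alone (camera adjusted p = 0.0147; adjusted p = 0.284 with an estimated correlation), led by the lipid-transfer family gene LOC101245586 (0.76 ± 0.13). That call was lost without Z3HP replicate 4 (camera adjusted p = 0.116) or MeSA replicate 2 (0.0807). Cell division genes had 1 higher and 3 lower of 192, 0 and 1 over the list alone (camera adjusted p = 0.00954; adjusted p = 0.631 with an estimated correlation). The call was lost without Z3HP replicate 2 (adjusted p = 0.228), MeSA replicate 2 (0.0538) or MeSA replicate 4 (0.0652). Ribosomal protein genes had 3 lower of 343, 0 over the list alone (camera adjusted p = 3.66e-07; adjusted p = 0.56 with an estimated correlation), with a list median of -0.103 and 50S ribosomal protein L7/L12 (LOC101262273) at -0.41 ± 0.08. The 3 lower genes became 13 without control replicate 4, 11 without Z3HP replicate 4 and 25 by DESeq2, but 1 by limma on FPKM.

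No other list was called between the volatiles. The numbers higher and lower in Z3HP were 1 and 0 of 46 jasmonate, 1 and 0 of 36 salicylate, 3 and 1 of 99 pathogenesis-related and 0 and 1 of 12 green leaf volatile genes. They were 2 and 0 of 118 ethylene, 5 and 0 of 115 auxin, 3 and 0 of 112 abscisate, 3 and 1 of 89 photosynthesis, 5 and 3 of 215 cell wall and 12 and 5 of 451 immune receptor genes. Among tissue markers 1 and 0 of 29 meristem and 2 and 0 of 57 flower genes passed. Photosynthesis genes stood at 5 higher and 9 lower without control replicate 4 and at 6 and 10 by DESeq2, so the balance turned, and at 6 and 5 by limma on FPKM. Cell wall genes stood at 9 and 11 by DESeq2 and 7 and 2 under library sizes alone, and immune receptor genes at 21 and 5 and at 10 and 1. EdgeR called 0 and 0 of 37 proteinase inhibitor, 39 terpenoid and 17 root genes. At an unadjusted p under 0.05 these were 2 and 2, 7 and 1, and 1 and 0, by DESeq2 0 and 2, 2 and 0, and 1 and 0, and by limma on FPKM 0 and 0, 1 and 0, and 0 and 0. The cell wall list (median -0.016, mean 0.009) and the root list (-0.009, 0.032) had a downward camera direction, so these signs differed. The pathogenesis-related list passed without Z3HP replicate 2 (camera adjusted p = 0.0251) and the auxin list without Z3HP replicate 3 (0.0452). The abscisate list passed without control replicate 4, Z3HP replicate 3 or MeSA replicate 1 (camera adjusted p = 0.0422 to 0.0455).

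Named members of these lists were OPR1 (0.43 ± 0.08), calmodulin-binding protein 60 D (LOC101245373, 0.35 ± 0.07), LOX1.1 (-1.31 ± 0.27), protein phosphatase 2C 57 (LOC101262900, 0.47 ± 0.06) and psbS of photoprotection (0.55 ± 0.09). Others were tXET-B1 of the cell wall (1.02 ± 0.15), the TMV resistance protein N-like gene LOC101266010 (1.12 ± 0.13), CLV2 (0.58 ± 0.14) and LOC101253793, a pollen Ole e I-like gene (0.57 ± 0.13). The CLV2 call was lost without Z3HP replicate 2, 3 or 4 or any 1 MeSA library (edgeR adjusted p = 0.0565 to 0.108), and with only Z3HP and MeSA in the model (0.0508). That of LOC101253793 was lost without Z3HP replicate 2, 3 or 4 or MeSA replicate 1, 2 or 3 (adjusted p = 0.0589 to 0.077). That of LOX1.1 was lost without Z3HP replicate 2 (edgeR adjusted p = 0.0613) or 3 (0.0527), and that of LOC101245373 without Z3HP replicate 2 (0.0659) or MeSA replicate 2 (0.0512).

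EdgeR called 0 of the 15 panel genes between the volatiles, against 4 higher and 1 lower at an unadjusted p under 0.05. SAMT stood at -0.50 ± 0.16 (edgeR adjusted p = 0.104). DESeq2 called AOS2 as higher in Z3HP (0.37, adjusted p = 0.0465) and SAMT as lower (adjusted p = 0.0409), and limma on FPKM called AOS2 (0.39, adjusted p = 0.0224). The 745 genes became 352 without Z3HP replicate 2, 395, 363 and 400 without MeSA replicates 1, 2 and 4, and 1078 without control replicate 4. The share higher in Z3HP was 65.4% with TMM factors, 75% with library sizes alone, and 78% and 77.4% on FPKM with pseudocounts of 1 and 0.1.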

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

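The tests of time of day, with and without REVEILLE 1, and of the volatiles themselves were chosen only after the result was seen. A library was singled out when its gap to the nearest of the 4 in its group took up most of their range (Dixon's test at the 95% level). This held for 23 of 372 sets of 4 values (6.18%), and chance gives about 1 in 20. Of these 11 were in control replicate 4.

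Control replicate 4 was highest for PAL3 (689 CPM against 422 to 440 in the other controls), LOC100125909 (184 against 121 to 131), dxs (248 against 199 to 203), LOC543836 (120 against 105 to 106), LOC100736525 (34.1 against 17.7 to 20), LOC101267358 (13.7 against 5.36 to 6.06) and tXET-B1 (3.06 against 2.52 to 2.61). It was lowest for LOC101055573 (29.2 CPM against 40.1 to 41.3), HSP90 (9.18 against 16.6 to 17.4), CLV2 (5.12 against 6.5 to 6.57) and its TMM factor (1.01 against 1.1 to 1.11). NIM1 was lowest in control replicate 3 (9.82 CPM against 13.5 to 14). Without control replicate 4 the counts of changed genes were 6521 for Z3HP and 5556 for MeSA against the controls, and 1078 between the volatiles.

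In Z3HP, replicate 2 was highest for LOC101253069 (54.3 CPM against 33.4 to 37) and LOC100125909 (358 against 309 to 316), replicate 3 was highest for LOC101256480 (98.6 against 73.9 to 77), and replicate 4 was lowest for LOC101259524 (49.2 against 65 to 65.9). In MeSA, replicate 1 was lowest for LOC101253772 (0.718 CPM against 1.3 to 1.37) and highest for LOC100037737 (136 against 110 to 112), and replicate 2 was lowest for LOC101261578 (10.6 against 14.4 to 14.8). MeSA replicate 3 was lowest for LOC101256061 (0.396 CPM against 0.561 to 0.592) and LOC101245373 (56.6 against 67.7 to 69.2), and highest for LOC101255145 (17.6 against 11.7 to 12.1) and LOX1.1 (3.38 against 1.75 to 1.89).

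Clock and day-length genes separated the controls from both volatiles. At least 42 of them passed between Z3HP and control whichever control library was left out, which argues against 1 aberrant control as the source. Against the controls, averaged over both volatiles, 7 morning genes (LNK1, PRR37, PRR73, LHY and REVEILLE 8 families) had a median log2 fold change of 0.34 and 13 evening genes (APRR1, GIGANTEA, PCL1, EARLY FLOWERING 3 and 4 and adagio 3 families) of -1.25, a difference of 1.59 (exact permutation p = 0.0676 over 77520 assignments). REVEILLE 1 (LOC101261079), also a dawn gene, was not in that set and went against it (-3.01 in Z3HP, -4.20 in MeSA), and with it the difference was 1.55 (exact permutation p = 0.115 over 203490 assignments). A difference in the hour or light state at harvest may underlie this. Both p values missed the threshold, but they treat related clock genes as independent and do not measure variation between plants, so they do not decide it. With separate controls the volatiles' fold changes over clock genes correlated at 0.97, as a response common to both would also give. Exposure, chamber and hour therefore cannot be told apart, since chamber and hour per group are not given in the sources used here.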

How the results depend on the processing

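Library sizes without scaling factors, Fisher's exact test, counts outside 3 lists and the ethylene list without methylene names were tests chosen only after the result was seen. With thresholds that added a 2-fold change the counts for Z3HP against control, MeSA against control and Z3HP against MeSA were 1529, 1229 and 256 at an unadjusted p under 0.05 and 1388, 1086 and 83 at the adjusted one. The latter are subsets of the 6039, 5143 and 745, while the former also dropped the adjustment, without which and with no minimum fold 8025, 7255 and 3745 genes passed. DESeq2 called 1399 genes between the volatiles, and the cause was not tested. Leaving out single libraries gave 5015 to 6521, 4160 to 5556 and 352 to 1078 genes, the lowest of the last without Z3HP replicate 2 and the highest without control replicate 4. The lists called were then 7 to 9, 3 to 6 and 6 to 10, with 3 in MeSA against control without control replicate 1 and 6 without control replicate 4. With an estimated correlation camera called 0, 0 and 1 lists, which allows for the members' own correlation. Fry, which tests whether a list's members move 1 way without comparing them with other genes, called 15 and 13 lists against the controls. It did not call some lists that camera called. These were cell division in Z3HP against control (fry adjusted p = 0.0833), and cell division (0.389) and ribosomal proteins (0.171) between the volatiles. Fisher's exact test called 5 lists between the volatiles, in either direction. For ribosomal proteins (Fisher adjusted p = 0.0105) the share of changed genes lay below the rest, with 3 of 343 against 3.7% of all tested genes. Among lists that camera called upward under library sizes alone, the median log2 fold change turned negative for phenylpropanoids (-0.061), abscisate (-0.012) and glutathione (-0.024) genes in Z3HP against control and for ethylene (-0.096) and abscisate (-0.056) genes in MeSA against control, where the median of all genes also lay lower, at -0.168 and -0.196. Medians of lists not called there turned negative too, among them immune receptors (-0.123) in Z3HP and auxin (-0.072) and glutathione (-0.095) genes in MeSA. With the controls split into separate pairs the overlap of both volatiles averaged 2388.8 genes and the correlation 0.603, with fewer controls in each part, and leaving out single libraries gave 3063 to 4259 genes and 0.774 to 0.834.

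Of the genes named by the rule, 70 of 75 stayed on their side of the threshold in Z3HP against control under every alternative run. So did 69 of 75 in MeSA against control and 36 of 44 between the volatiles, and no call reversed. Sign changes of genes that did not pass were not counted. Over lists and alternatives 1158 results stayed, 47 lost and 35 gained a call. In 5 more, all under library sizes alone, a list called in the main or that setting had a median of the opposite sign. Lists called in neither counted as staying whatever their sign. Among them were cell wall genes in MeSA against control, with a median of -0.019, and of 0.088 without control replicate 4. Replicate numbers did not pair the libraries. The 12 same-number pairs had correlations of -0.061 to 0.047 between their deviations from the group means, 0 of them over 0.1, and 1 of 12 libraries correlated best with its own number. With the number as a block 5661, 4808 and 521 genes were called and 7, 5 and 7 lists, 3562 genes changed with both volatiles and the correlation was 0.821. Glutathione lost its call in Z3HP against control (camera adjusted p = 0.0576) and clock genes lost theirs between the volatiles (0.0533). Of named genes CLV2 (edgeR adjusted p = 0.0689), LOC101253793 (0.0651), LOX1.1 (0.0595) and LOC101267358 (0.0557) lost their calls between the volatiles and SAMT gained one in Z3HP against control (0.0284), and the block changed no other call of a list or named gene. In the simulated counts at n = 4, changes of 0.5 on the log2 scale were recovered at 22.7% for Z3HP against control and 24.2% between the volatiles. Changes of 2 were recovered at 97% in both. A smaller share of genes was changed there than in the data, so these shares need not carry over. Genes at a few counts are uncertain as well, but recovery was not compared by count level.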

Other observations

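The tests of a chamber condition, of 1 library moving the whole list and of the clock shift over all list members, and the small heat shock, flavonoid and lignin genes named, were chosen only after the result was seen. For Z3HP against control the real grouping gave 5436 genes and the highest of the other splits of the 8 libraries 3, for MeSA against control 5014 and 2, and for Z3HP against MeSA 682 and 4, in fits of the 2 groups compared. Only 1 of 35 splits, the real one, gave as many genes in each comparison, a share under 0.05 and the smallest that 35 splits can give. That argues against chance in how single plants were divided. The other splits mix groups that differ, which raises the spread and lowers their counts. Plants of a group may have shared a chamber and an hour, so chance differences between chambers are not covered.

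The small heat shock genes HSP17.4 and vis1 stood highest in MeSA. HSP17.4 had means of 0.297 CPM in the controls, 0.157 in Z3HP and 1.72 in MeSA (Z3HP against MeSA log2 -3.40 ± 0.57, edgeR adjusted p = 0.00499), and vis1 0.898, 1.17 and 4.31. The heat stress transcription factor A-6b (LOC101266155) had 0.382, 0.1 and 2.16 CPM. The abundant HSC80 stood at 1190, 1290 and 2050 CPM (-0.67 ± 0.15). On the flavonoid side AnthOMT had 72.6, 64.8 and 22.3 CPM in the same order (1.54 ± 0.21) and F3H 50.3, 44.6 and 25.6, so that for these MeSA was the lowest group. On the lignin side caffeic acid 3-O-methyltransferase 1 (LOC101260288) had 60.4, 93 and 72.5 CPM (0.36 ± 0.07), highest in Z3HP.

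Heat shock genes were higher in MeSA than in Z3HP. At least 13 of the 17 passed whichever library of either volatile was left out, which argues against 1 aberrant library. A continuation of the shift between controls and exposed plants, read from clock genes, predicted a median difference of -0.01. Over the 17 genes, which were selected for differing, -1.38 was observed. Over all 80 members the prediction was -0.002 against -0.183 (95% interval from resampled members -0.256 to -0.102). That interval treats members as independent and holds no variation between plants. The slope over clock genes was -0.033, with an interval of -0.098 to 0.026, so any list would get a very small prediction. The values argue against a proportional continuation of that shift as the whole source, but not against another difference in the hour of harvest. With TMM factors 26 heat shock genes were higher and 9 lower in MeSA than in the controls, and 11 higher and 24 lower in Z3HP. Under library sizes alone the numbers in MeSA were 18 and 19. Temperature or another condition of the chamber may have contributed, which these counts do not tell from an effect of the volatile. Chamber, hour of harvest and volatile cannot be told apart, because the chamber and hour of each group are not given in the sources used here. Clock genes also differed between the volatiles, with 8 higher and 1 lower in Z3HP of 60.

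Phenylpropanoid genes were lower in MeSA than in Z3HP. The shift read from clock genes predicted a median of 0.013 against 0.64 observed over the 27 genes selected for differing, and of 0.001 against 0.315 over all 113 members (95% interval from resampled members 0.18 to 0.405). These values argue against a proportional continuation of that shift as the whole source, with the same limits of slope and interval as for heat shock genes. They leave another difference in the hour of harvest open. Under library sizes alone 27 genes passed, but that setting moved all genes toward Z3HP (median 0.034 against 0.006), so it tests little. With upper-quartile scaling, where the median of all genes was -0.012, 21 passed, which argues against the scaling as the whole source. Without MeSA replicate 1, 12 genes passed, which lies between the bounds set for 1 aberrant library, so a part played by that library stays open. The volatile, the chamber and the hour of harvest stay open too, and were not tested apart. The median of the whole list was at least 0.267 whichever library was left out, which argues against 1 library moving the whole list.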
